A study of Homo sapiens with 45 samples.

How the data were processed

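RNA from skin tape strips was profiled in 45 people, 18 healthy controls (Control) and patients with Netherton syndrome (NS, 9), congenital ichthyosiform erythroderma (CIE, 6), lamellar ichthyosis (LI, 7) and epidermolytic ichthyosis (EI, 5), 1 library each. Per the labels' protocols, RNA was purified with the Qiagen miRNeasy kit and 5 ng went into poly(A) selected libraries with the Illumina TruSeq Stranded mRNA kit. Per the submitters' processing notes, reads were trimmed with cutadapt 1.9.1, checked with FastQC 0.11.5, aligned to GRCh37 with STAR 2.4.2a and counted with featureCounts 1.5.0-p2, and the authors then used edgeR and limma. The sources give neither the strand setting of the counting nor the handling of reads with several matches, which matters for genes in families of near-identical copies (the SPRR2, LCE3, S100A7 and DEFB4 genes, SERPINB3 and ribosomal proteins) and for genes overlapping others (HRNR, MGAM).

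The deposited table holds log2 values for 11832 genes in 45 columns, as log2 of reads plus 0.5 per M of a scaled library size (CPM, counts per M reads). The reads behind each value were worked back from that formula: 100 percent of the values gave a whole read within 0.01. The smallest value of a library therefore marks 0 reads. Libraries held 0.112 to 19.6 M recovered reads, 5 of them fewer than 1 M, so 1 read weighs several CPM in the shallowest. A fold change against a group without a read is given as a lower bound that takes 3 reads over that group as its limit. Such a bound is a ratio of reads pooled over each group, not on the scale of the limma changes. It does not allow for transcripts lost before sequencing. Genes of the 2 sex chromosomes that differ between men and women (11) were left out, leaving 11821. No 2 libraries were duplicates (highest correlation 0.951). Chromosomes, exon numbers and overlaps of genes were taken by symbol from a GENCODE annotation of a later genome build than that of the alignment. Mitochondrially encoded genes were not analysed here, with 0 of 13 measured. IL17C and CXCL8 were not analysed here either.

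Groups follow the sample labels. The main analysis fitted limma 3.58.1 in R 4.3.3 to the log2 values as deposited, with 1 mean per group over all 45 libraries and empirical Bayes moderation with an intensity trend. There were 11 contrasts: each disease against Control, the mean of the 4 against Control and the 6 disease pairs. A gene passed with a fold change over 2 and an adjusted p under 0.05 (Benjamini-Hochberg). A library counts as higher where it lies above the median of the other group and has a read of the gene. The 37 gene lists were fixed from general knowledge before the values were seen. They cover cytokine axes, immune cells, epidermal layers, barrier and junction genes, appendages, other cells of skin and stress programs. 35 of them, with 3 or more measured genes, were tested with fry, a rotation test of limma, and for each the genes passing with p adjusted over the list alone were counted too. Depth and olfactory receptor shares were compared by exact permutation of group labels, enumerating every split, 2-sided.

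Genes to name were chosen by a rule written before the values were seen: among genes that passed and whose mean lies above percentile 25, the 8 largest rises and 6 largest falls of each disease, 5 each way for other contrasts, up to 4 members of each called list and 2 of other lists, plus 24 genes fixed beforehand, such as SPINK5, KRT1, FLG and IL13. The text prints a part of them. Tests were tried on simulated data: of 100 genes changed by log2 3, 90 percent were recovered in NS, 77 in CIE, 84 in LI and 74 in EI, and at log2 5 99, 97, 100 and 91 percent, while among 11621 unchanged genes at most 11 were called in 1 direction in any of these. The same was done between NS and CIE, NS and LI, and CIE and LI, with the change in the first disease alone. Simulated genes varied independently of each other and simulated libraries of a group differed in depth alone. Recovery in the real libraries can therefore be lower and false calls more frequent. Each count was compared with 100 splits of the same libraries into groups of the same sizes, the real split included. What shared controls alone do to overlaps and correlations was taken from 100 simulations without a change (the overlaps of pairs were added after seeing the data) and 100 splits of the controls into 2 sets of 9.

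Alternatives fixed before the values were seen were quantile normalization, equal library medians, the upper part of genes by mean, no trend, a robust prior, sample quality weights, the number of detected genes as a covariate, only the groups compared, the replicate number as a replicate block, leaving out each library, voom weights on recovered reads and camera with preset (0.01) or estimated correlation. Count tests with DESeq2 and edgeR and another pseudocount had been planned only for a file in a linear unit and were not run. Added after seeing the data were a quasi-likelihood negative binomial model on the recovered reads (MASS 7.3.60.0.1 and limma), leaving out libraries under 1 M reads, strata of 1 to 5 and over 5 M reads, thinning to 1 M reads (without libraries under that), the recovered in place of the scaled library sizes, leaving out 4 Control libraries with NEUROG1 reads, 8 libraries with over 5000 olfactory receptor CPM or NS replicates 4 and 6, and the olfactory receptor share as a covariate. Outlying values were sought with Dixon tests at 5 percent. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.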

Results

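Adhesive tape lifts the outermost layers of the skin without a biopsy. Here it was used to compare RNA from 18 healthy controls (Control) with that of 27 people with 1 of 4 inherited ichthyoses, disorders in which a faulty barrier leaves the skin scaly and inflamed. Netherton syndrome (NS, 9 patients) follows loss of the protease inhibitor encoded by SPINK5. Congenital ichthyosiform erythroderma (CIE, 6) and lamellar ichthyosis (LI, 7) arise mostly from genes of the lipid and protein envelope such as TGM1, ALOX12B and NIPAL4, and epidermolytic ichthyosis (EI, 5) from the suprabasal keratins KRT1 and KRT10. All 4 shared a rise of IL-17 and TNF induced epidermal genes, beta-defensin 2 (DEFB4A) among them. The list of Th17 cytokines and receptors itself was called by fry in NS and CIE. It was not called in LI (adjusted p = 0.0585) or in EI (adjusted p = 0.497), where IL17A had 1 read. Basal keratinocyte genes fell in all 4, a weaker list result that kept its call in none of them with an estimated correlation (adjusted p 0.0565, 0.211, 0.339 and 0.564 in NS, CIE, LI and EI). The IL-17 and TNF list lost its call that way in EI alone (0.0862). The T cell, Th2 and dendritic cell lists had their largest median rise in NS and the neutrophil list in LI. Changes are log2 fold changes ± standard error against Control, with p adjusted by the Benjamini-Hochberg method in limma, and gene lists were tested with fry. Values given with an estimated correlation come from camera, which asks another question. It sets a list against all other genes, while fry asks whether the genes of the list moved at all. A call lost that way is therefore not a loss to correlation between genes alone.

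Depth differed between Control and some of the patient groups and bears on the comparisons that hold them. Median reads per library were 5.83 M in Control, 5.82 M in NS, 2.30 M in CIE, 2.78 M in LI and 1.21 M in EI. EI libraries held fewer reads than Control (mean log10 reads 5.92 ± 0.41, standard deviation, against 6.70 ± 0.30, exact permutation test with n = 5 and 18, p = 0.000416) and fewer genes with a read (6398 ± 1508 against 9715 ± 1450, p = 0.000654), each with adjusted p = 0.00262 over 8 tests. LI libraries also held fewer reads (6.26 ± 0.49, exact permutation test with n = 7 and 18, p = 0.0106, adjusted 0.0282), and no difference passed in NS or CIE. The median gene held 3 reads or fewer in 5 of 5 EI libraries and in 2 of 18 Control libraries. Reads on olfactory receptor genes, which skin does not normally transcribe, had medians of 4387 counts per M reads (CPM) in EI, 1844 in LI, 1825 in CIE, 219 in NS and 75.8 in Control. Patient profiles were most alike in NS, with a median correlation between libraries of 0.715 against 0.555 in Control, 0.49 in CIE, 0.557 in LI and 0.470 in EI.

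**Figure D1:**
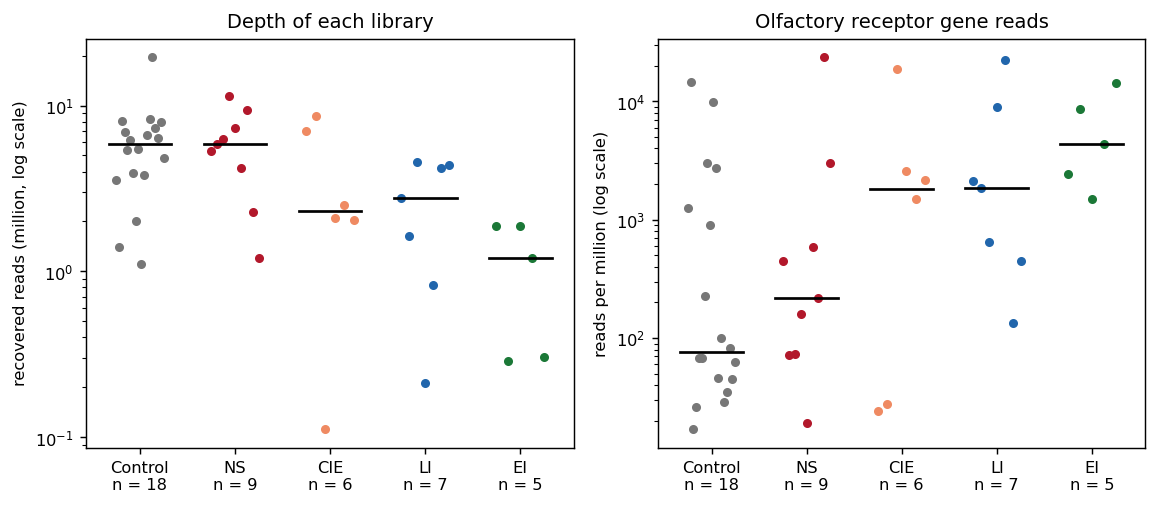
Recovered reads (left) and olfactory receptor gene CPM (right) of each library, by group. Dots are libraries, bars are medians, both axes are on a log scale.

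In NS, 1113 genes rose and 814 fell. The largest rises were in DEFB4A, which encodes beta-defensin 2 (9.19 ± 1.05, adjusted p = 3.09e-08), and in LCE3A, a late cornified envelope gene switched on in injured epidermis (8.47 ± 1.02, adjusted p = 9.33e-08). Both were above the Control median in 9 of 9 libraries. OASL, an antiviral interferon target (7.81 ± 0.99), the neutrophil alarmin S100A12 (7.52 ± 1.09), the neutrophil attractant CXCL1 (7.28 ± 1.17), the TSLP receptor chain CRLF2 (7.29 ± 1.17) and the lymphocyte adaptor SAMSN1 (7.23 ± 1.13) followed. Each had adjusted p at most 1.14e-05, with 9 of 9 libraries higher. OR2B11 also rose (7.45 ± 0.98, adjusted p = 8.56e-07). It lies beside the inflammasome gene NLRP3, so its reads can belong to that neighbour. Genes that keratinocytes switch on under IL-17 and TNF gave the clearest group: 30 of 33 rose, 31 higher when adjusted over the list alone, adjusted p = 6.02e-08, among them S100A8 (6.01), SERPINB3 (6.90) and IL36G (6.04). Wound-type and hyperplasia genes were mixed (8 of 24 rose and 1 fell, 9 higher when adjusted over the list alone, adjusted p = 0.0133, adjusted p = 0.315 with an estimated correlation). Of these, SPRR2F (7.14) and LCE3D (5.31) rose, while KRT6A (-0.52 ± 0.67, adjusted p = 0.697) and KRT16 (-0.48 ± 0.69, adjusted p = 0.731) did not pass.

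Immune cell genes rose broadly in NS. Of the T and cytotoxic cell genes, 16 of 17 rose, adjusted p = 3.85e-07, with granzyme B (GZMB, 6.45) and CD3E (4.89). Dendritic and Langerhans cell genes (22 of 24 rose, adjusted p = 1.18e-05) included IRF8 (5.96) and the costimulator CD86 (6.14). Macrophage genes (15 of 15 rose, adjusted p = 5.81e-06) included lysozyme (LYZ, 4.66) and complement C1QC (5.46). Neutrophil genes (19 of 21 rose, 20 higher when adjusted over the list alone, adjusted p = 5.81e-06) included the receptors FPR2 (6.88) and FCGR3B (5.57). The immune regulators ICOS (5.83) and TIGIT (4.57) belonged to a list in which 12 of 14 rose and 1 fell, 13 higher when adjusted over the list alone, adjusted p = 1.06e-06. In the IL-1 list 12 of 22 rose, 13 higher when adjusted over the list alone, adjusted p = 5.81e-06, with IL1B (6.0) and IL6 (4.88). These named genes each had adjusted p at most 0.000413, with 8 or more of 9 libraries above the Control median. Immediate early genes, which also mark handling stress (7 of 17 rose, 9 higher when adjusted over the list alone, adjusted p = 0.000777, adjusted p = 0.166 with an estimated correlation), included NR4A2 (4.78 ± 0.93, adjusted p = 0.000171).

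Cytokine axes of several kinds were raised together in NS. IL17A, the Th17 cytokine, had 1452 reads in 8 of 9 NS libraries and 0 in 18 Control libraries, a rise of at least 1260-fold (adjusted p = 8.56e-07). IL22 (4.27) and the IL-12/23 chain IL12B (5.33) rose from 9 and 33 Control reads. Over the Th17 list 5 of 12 rose and 2 fell, 8 higher when adjusted over the list alone, adjusted p = 7.41e-05, adjusted p = 0.11 with an estimated correlation. It was not called among libraries of 1 to 5 M reads (adjusted p = 0.103) or in the upper part of genes by mean, where its median turned to -1.43 (adjusted p = 0.419). In the Th2 axis, 10 of 19 rose and 1 fell, 11 higher and 2 lower when adjusted over the list alone, adjusted p = 2.00e-05, adjusted p = 0.0565 with an estimated correlation. The receptor IL4R (4.30), IL7R (6.40), IL13 (4.24) and the chemokine CCL22 (3.50) rose, while CCL17 (3.13 ± 1.25, adjusted p = 0.0779) did not pass. Th1 genes (6 of 14 rose, 10 higher when adjusted over the list alone, adjusted p = 0.000238, adjusted p = 0.0893 with an estimated correlation) included GBP5 (5.37) and CXCL10 (3.71). Type I interferon genes (18 of 28 rose, 22 higher when adjusted over the list alone, adjusted p = 1.18e-05) included ISG15 (5.42), MX2 (4.43) and MX1 (3.87). JAK-STAT feedback and signal genes such as SOCS3 (3.43) and STAT4 (3.89) rose (7 of 15 rose, 8 higher when adjusted over the list alone, adjusted p = 7.97e-06). Endothelial genes (2 of 6 rose, 3 higher when adjusted over the list alone, adjusted p = 2.63e-05, adjusted p = 0.0784 with an estimated correlation) included VWF (5.52) and ENG (3.41). Each gene said to rise here had adjusted p at most 0.0108, with 7 or more of 9 libraries higher.

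Genes of the living basal layer fell in NS. CXCL14, a chemokine of resting epidermis (-10.06 ± 1.37), the basal keratins KRT15 (-8.84 ± 1.31), KRT5 (-7.90 ± 1.23) and KRT14 (-4.69 ± 0.77) and connexin 43 (GJA1, -8.08 ± 1.20) were among them. So were the protease inhibitor-like WFDC3 (-8.07 ± 1.17) and MIR205HG, host of a keratinocyte microRNA (-7.76 ± 1.27). All 7 were lower in 9 of 9 libraries, with adjusted p at most 1.38e-05. Basal keratinocyte genes fell as a list (9 of 16 fell, 12 lower when adjusted over the list alone, adjusted p = 0.000129, adjusted p = 0.0565 with an estimated correlation). Junction genes (6 of 20 fell, 7 lower when adjusted over the list alone, adjusted p = 0.000829, adjusted p = 0.0893 with an estimated correlation) fell through CLDN4 (-3.49). Dermal matrix genes (7 of 12 fell and 1 rose, adjusted p = 0.00187, adjusted p = 0.125 with an estimated correlation) fell through DCN (-6.34) and COL3A1 (-5.38), these 3 genes with adjusted p at most 0.000414. Hair genes fell (5 of 20 fell, adjusted p = 0.046, adjusted p = 0.284 with an estimated correlation). The hair call was lost in 13 of 27 fits with 1 library left out and turned direction among libraries of 1 to 5 M reads. The count depends on the libraries used. 21 genes passed among libraries of 1 to 5 M reads (3 NS, 7 Control), all higher. Over 5 M reads (6 NS, 11 Control) 4612 passed, 1844 higher and 2768 lower. With every library thinned to 1 M reads 1777 passed. Of the genes printed for NS, DEFB4A, LCE3A, OASL, SPRR2F, SERPINB3, S100A8, LCE3D and IL17A passed in every alternative. The others lost their call at least among the libraries of 1 to 5 M reads.

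**Figure D2:**
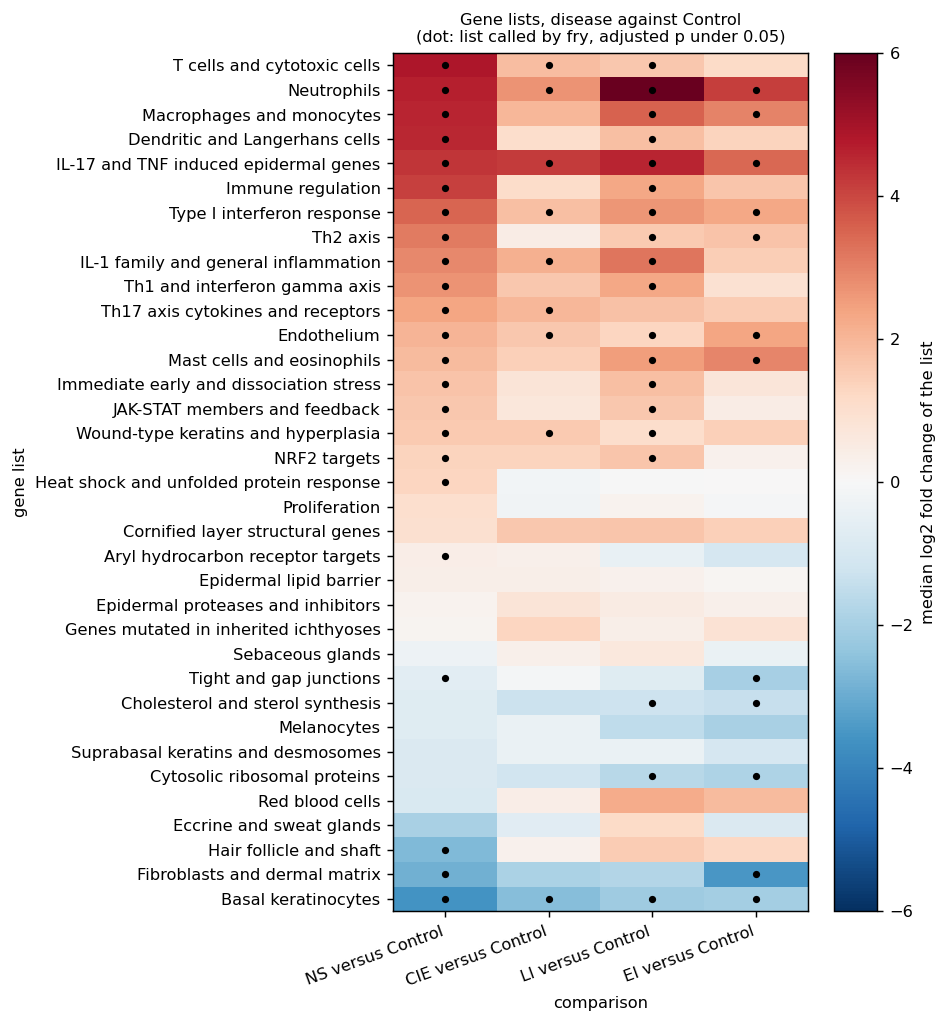
Median log2 fold change of each gene list in the 4 comparisons with Control. A dot marks a list called by fry at adjusted p under 0.05.

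In CIE, 63 genes rose and 85 fell, and the IL-17 and TNF list was the clearest rise. DEFB4A (8.77 ± 1.21), the koebnerisin gene S100A7A (8.64 ± 1.26), the Th17 cell attractant CCL20 (7.59 ± 1.18), LCE3A (7.43 ± 1.17), SERPINB3 (7.25 ± 1.09), S100A12 (7.15 ± 1.26) and S100A8 (6.19 ± 0.93) rose. So did the cornified envelope precursors SPRR2F (7.26 ± 1.16), SPRR2D (5.96 ± 0.93) and SPRR2E (5.14 ± 0.82), OASL (7.99 ± 1.14) and endothelial VWF (6.55 ± 1.07). Each was higher in 6 of 6 libraries (S100A12 in 5, with 0 reads in the other), with adjusted p at most 0.000311, and kept its call with any 1 library left out. IL-17 and TNF induced genes (15 of 33 rose, 26 higher when adjusted over the list alone, adjusted p = 6.71e-06) and endothelial genes (1 of 6 rose, adjusted p = 0.000463) rose as lists. IL17A itself had 93 reads in 2 of 6 libraries and 0 in Control, at least 187-fold in pooled reads, but did not pass (adjusted p = 0.0589). Further lists were called but lost the call with an estimated correlation. Of the wound-type genes 6 of 24 rose, 8 higher when adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.0634 with an estimated correlation. Of the IL-1 genes 1 of 22 rose, 8 higher when adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.0634 with an estimated correlation. Among neutrophil genes 0 of 21 rose, 10 higher when adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.0634 with an estimated correlation, and among Th17 genes 0 of 12 rose, 6 higher when adjusted over the list alone, adjusted p = 0.0329, adjusted p = 0.0817 with an estimated correlation. Type I interferon genes (2 of 28 rose, 6 higher when adjusted over the list alone, adjusted p = 0.0431, adjusted p = 0.0855 with an estimated correlation) and T cell genes (0 of 17 rose, 2 higher when adjusted over the list alone, adjusted p = 0.0465, adjusted p = 0.102 with an estimated correlation) were weaker.

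Basal keratins were among the falls in CIE. KRT15 (-6.21 ± 1.52), KRT5 (-5.54 ± 1.43), KRT14 (-3.49 ± 0.88), WFDC3 (-5.95 ± 1.35), MIR205HG (-5.38 ± 1.46), the lipid carrier APOE (-6.0 ± 1.29) and the mitochondrial HIGD2A (-5.22 ± 1.21) fell. All were lower in 6 of 6 libraries, with adjusted p of at most 0.0449. Basal keratinocyte genes fell as a list (3 of 16 fell, 6 lower when adjusted over the list alone, adjusted p = 0.0266, adjusted p = 0.211 with an estimated correlation). IL36G (6.21 ± 1.38), the protease inhibitor SERPINB7 (4.68 ± 1.09), the envelope gene CNFN (3.59 ± 0.90), IL1B (4.47 ± 1.11), CD80 (4.58 ± 1.10) and IRF8 (3.80 ± 0.97) rose (adjusted p at most 0.0353). Of the 9 lists called in CIE, only the IL-17 and TNF and the endothelial list kept the call with any 1 library left out. All 13 of these gene calls were lost with some single library left out. Without CIE replicate 5 the count of changed genes was 29, and without CIE replicate 1 it was 484. Among libraries of 1 to 5 M reads (3 CIE, 7 Control) 15 genes passed and over 5 M (2 CIE, 11 Control) 98. The share higher was 42.6 percent as deposited, 61.3 percent after quantile normalization and 95.5 percent with equal medians. The all-gene median moved from -0.53 to -0.02 and 0.60.

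In LI, 952 genes rose and 521 fell, and neutrophil genes led the rises. FPR2, a receptor for bacterial peptides (7.87 ± 1.30), the granulocyte receptor CEACAM3 (7.68 ± 1.31), the Fc receptor FCGR3B (7.54 ± 1.07) and the IL-8 receptor CXCR1 (6.71 ± 1.12) rose. All were higher in 7 of 7 libraries, with adjusted p at most 6.47e-05. Over the neutrophil list 19 of 21 rose, adjusted p = 1.21e-06. MGAM, a glucosidase carried by neutrophils, showed the largest rise (8.72 ± 1.08, adjusted p = 5.49e-07). CLEC5A and an olfactory receptor gene overlap it. Epidermal alarm genes rose beside them. DEFB4A (7.74 ± 1.14), CCL20 (7.84 ± 1.11), S100A12 (7.65 ± 1.19), S100A9 (6.14 ± 0.84), S100A8 (6.13 ± 0.88), CXCL1 (7.60 ± 1.28) and IL36G (5.67 ± 1.30) were higher in 7 of 7 libraries, with adjusted p at most 0.0027. In the IL-17 and TNF list 22 of 33 rose, 26 higher when adjusted over the list alone, adjusted p = 1.21e-06. These 2 lists were the only ones in LI that stayed called with an estimated correlation.

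Other immune programs rose in LI as well. IL-1 family genes (12 of 22 rose, 14 higher when adjusted over the list alone, adjusted p = 0.000104, adjusted p = 0.0913 with an estimated correlation) included IL1B (6.83), OSM (6.82) and PTGS2 (5.42). Macrophage genes (9 of 15 rose, 12 higher when adjusted over the list alone, adjusted p = 0.00075, adjusted p = 0.147 with an estimated correlation) included CD14 (5.84) and FCGR2A (6.67). JAK-STAT genes (2 of 15 rose, 4 higher when adjusted over the list alone, adjusted p = 0.000293, adjusted p = 0.136 with an estimated correlation) included JAK3 (5.47) and SOCS3 (4.11). Type I interferon genes (10 of 28 rose, 17 higher when adjusted over the list alone, adjusted p = 0.001, adjusted p = 0.152 with an estimated correlation) included MX2 (5.21) and OASL (5.23). Th1 genes (3 of 14 rose, 5 higher when adjusted over the list alone, adjusted p = 0.0036, adjusted p = 0.189 with an estimated correlation) included GBP5 (5.29) and CXCL10 (4.47). The Th2 list (4 of 19 rose and 1 fell, 5 higher when adjusted over the list alone, adjusted p = 0.0141, adjusted p = 0.294 with an estimated correlation) rose through IL4R (4.21) and IL10 (4.50). IL13 had 4 reads in 1 library and CCL22 (0.52 ± 1.11, adjusted p = 0.786) did not pass. T cell genes (4 of 17 rose, adjusted p = 0.0291, adjusted p = 0.339 with an estimated correlation) included GZMB (4.39). Dendritic cell genes (7 of 24 rose, 9 higher when adjusted over the list alone, adjusted p = 0.0434, adjusted p = 0.339 with an estimated correlation) included ITGAX (5.22). Immediate early genes (6 of 17 rose, 7 higher when adjusted over the list alone, adjusted p = 0.001, adjusted p = 0.189 with an estimated correlation) rose with FOS (5.18). Immune regulation genes (5 of 14 rose, 7 higher when adjusted over the list alone, adjusted p = 0.00573, adjusted p = 0.225 with an estimated correlation) rose with TNFAIP3 (3.80). Endothelial genes (1 of 6 rose, adjusted p = 0.001, adjusted p = 0.189 with an estimated correlation) rose with VWF (6.24), and wound-type genes (7 of 24 rose and 1 fell, 8 higher when adjusted over the list alone, adjusted p = 0.0434, adjusted p = 0.361 with an estimated correlation) with SPRR2D (5.60) and SPRR2E (4.79). The lipase LIPN of the outer epidermis rose as well (3.95). These genes had adjusted p at most 0.0138, each higher in 7 of 7 libraries but for IL10, GZMB and CXCL10, which had reads in 5 and 0 in the other 2.

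The falls in LI were led by GLI3, a hedgehog pathway factor (-6.0 ± 1.07, 7 reads in 2 of 7 libraries). KRT15 (-5.97 ± 1.43), the matrix gene EFEMP1 (-5.66 ± 1.32), LURAP1L (-5.65 ± 1.35) and MIR205HG (-5.46 ± 1.38) followed. These 5 had adjusted p at most 0.00653 and were lower in 7 of 7 libraries, and PIK3C2G had 2 reads over the 7 LI libraries. Basal keratinocyte genes (4 of 16 fell, 6 lower when adjusted over the list alone, adjusted p = 0.0438, adjusted p = 0.339 with an estimated correlation) fell through KRT14 (-3.25). Sterol synthesis genes (4 of 18 fell, adjusted p = 0.0261, adjusted p = 0.339 with an estimated correlation) fell through NSDHL (-3.95). Ribosomal protein genes (15 of 32 fell, 25 lower when adjusted over the list alone, adjusted p = 0.00396, adjusted p = 0.225 with an estimated correlation) fell through RPLP1 (-2.12) and RPS6 (-2.02). Claudin 1 (CLDN1, -3.01), a seal of the granular layer, fell too (adjusted p at most 0.00756 for these 5). Olfactory receptor genes made up 111 of the 952 rises, out of 285 measured, and other single-exon genes 87. Among libraries of 1 to 5 M reads (5 LI, 7 Control) 10 genes passed, all higher. Without libraries under 1 M reads (the same 5 LI, 18 Control) 1163 did, and with every library thinned to 1 M reads 894. Of the 19 lists called in LI, 13 kept the call with any 1 library left out. The basal list lost it in 17 of 25 such fits, the dendritic cell list in 15 and the wound-type list in 13. The share higher was 64.6 percent as deposited, 47.6 percent after quantile normalization and 52.4 percent with equal medians.

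In EI, 743 genes rose and 2555 fell. DEFB4A (7.53 ± 1.30), LCE3A (7.00 ± 1.26), the elastase inhibitor PI3 (6.76 ± 1.21), S100A8 (5.36 ± 1.0), S100A9 (5.03 ± 0.96) and SPRR2D (5.06 ± 1.0) were each higher in 5 of 5 libraries (adjusted p at most 0.000323). HRNR, a filaggrin-like gene that an antisense transcript overlaps (7.63 ± 1.35), the keratinocyte differentiation factor CEBPA (7.65 ± 1.5), the stress chaperone HSPA6 (6.73 ± 1.19), OR2B11 (6.79 ± 1.22) and the immune checkpoint gene CD276 (6.65 ± 1.33) completed the largest rises (adjusted p at most 0.000362). CEBPA, HSPA6 and OR2B11 have a single coding exon. The IL-17 and TNF list rose (18 of 33 rose, 19 higher when adjusted over the list alone, adjusted p = 0.00242, adjusted p = 0.0862 with an estimated correlation). So did the neutrophil list (15 of 21 rose, 18 higher when adjusted over the list alone, adjusted p = 0.00242, adjusted p = 0.0862 with an estimated correlation), with FCGR3B (6.31) and FPR2 (6.20). Macrophage genes (5 of 15 rose, 9 higher when adjusted over the list alone, adjusted p = 0.0231, adjusted p = 0.171 with an estimated correlation) included FCGR2A (5.72). Type I interferon genes (10 of 28 rose, 11 higher when adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.155 with an estimated correlation) included OASL (5.08) and IFI44L (4.51). The Th2 list (3 of 19 rose, adjusted p = 0.0433, adjusted p = 0.155 with an estimated correlation) included IL4R (4.69). VWF (6.58) led the endothelial list (3 of 6 rose, adjusted p = 0.000256, adjusted p = 0.0862 with an estimated correlation), in which CLDN5 rested on 6 EI reads. CSF3 (5.83), IL1B (5.45) and the mitotic kinase AURKB (4.42) rose outside called lists. These later genes had adjusted p at most 0.00397, with 3 or more of 5 libraries higher.

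Falls in EI reached genes with 0 EI reads. Of the genes that passed, 349 had 0 reads throughout EI or throughout Control. Named among those without EI reads were SOSTDC1, a BMP and Wnt antagonist of the hair follicle (at least 1140-fold in pooled reads), and the splicing core protein SNRPD1 (at least 224-fold). The signalosome subunit COPS8 (at least 210-fold) and COL3A1 (at least 149-fold) were others (adjusted p at most 0.0016). The median gene had 0 to 2 reads in EI libraries, so transcripts missed in poor libraries can give such zeros too. KRT15 (-7.82 ± 1.63), KRT5 (-7.62 ± 1.53), KRT14 (-3.96 ± 0.95) and CXCL14 (-7.63 ± 1.70) were lower in 5 of 5 libraries (adjusted p at most 0.00215), and POSTN and NSDHL had 2 EI reads each. Basal genes fell as a list (5 of 16 fell, adjusted p = 0.0241, adjusted p = 0.564 with an estimated correlation). Dermal matrix genes (7 of 12 fell, adjusted p = 0.00765, adjusted p = 0.426 with an estimated correlation) fell through DCN (-5.19). Junction genes (6 of 20 fell and 2 rose, 7 lower when adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.754 with an estimated correlation) fell through CLDN1 (-4.38) and OCLN (-3.35). Sterol synthesis genes (4 of 18 fell, adjusted p = 0.0192, adjusted p = 0.661 with an estimated correlation) fell through MVD (-4.44). Ribosomal protein genes (19 of 32 fell, 26 lower when adjusted over the list alone, adjusted p = 0.0118, adjusted p = 0.43 with an estimated correlation) fell through RPL5 (-3.30) and RPS6 (-2.45), RPL5 not without EI replicate 5. These 6 genes had adjusted p at most 0.00479. Of the 12 lists called in EI, 4 kept the call with any 1 library left out. The excess of falls stayed with the recovered library sizes, while methods that centre the libraries moved the split by acting on all genes of a library. 22.5 percent of called genes were higher as deposited, 33.4 percent with the recovered library sizes, 52.9 percent after quantile normalization and 95.6 percent with equal medians, with all-gene medians of -1.23, -0.91, -0.04 and 1.43. With equal medians the sterol, junction, ribosomal and basal lists turned upward. The basal list also turned with the number of detected genes as a covariate and among libraries of 1 to 5 M reads. In that stratum (3 EI, 7 Control) 0 genes and 0 lists passed.

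**Figure D3:**
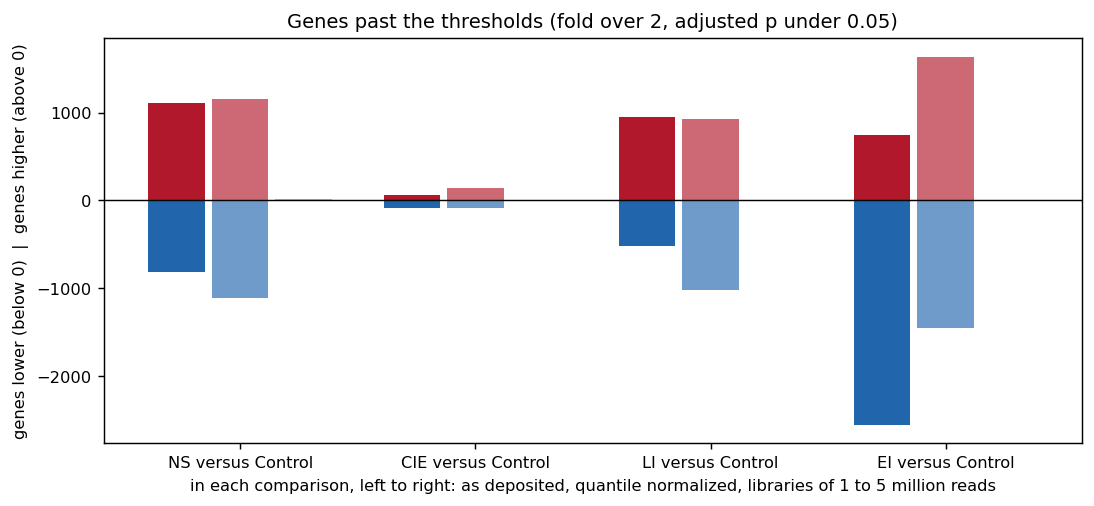
Genes higher (above 0) and lower (below 0) in each disease against Control. Bars in each group show, left to right, the values as deposited, after quantile normalization and among libraries of 1 to 5 M reads.

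**Figure D4:**
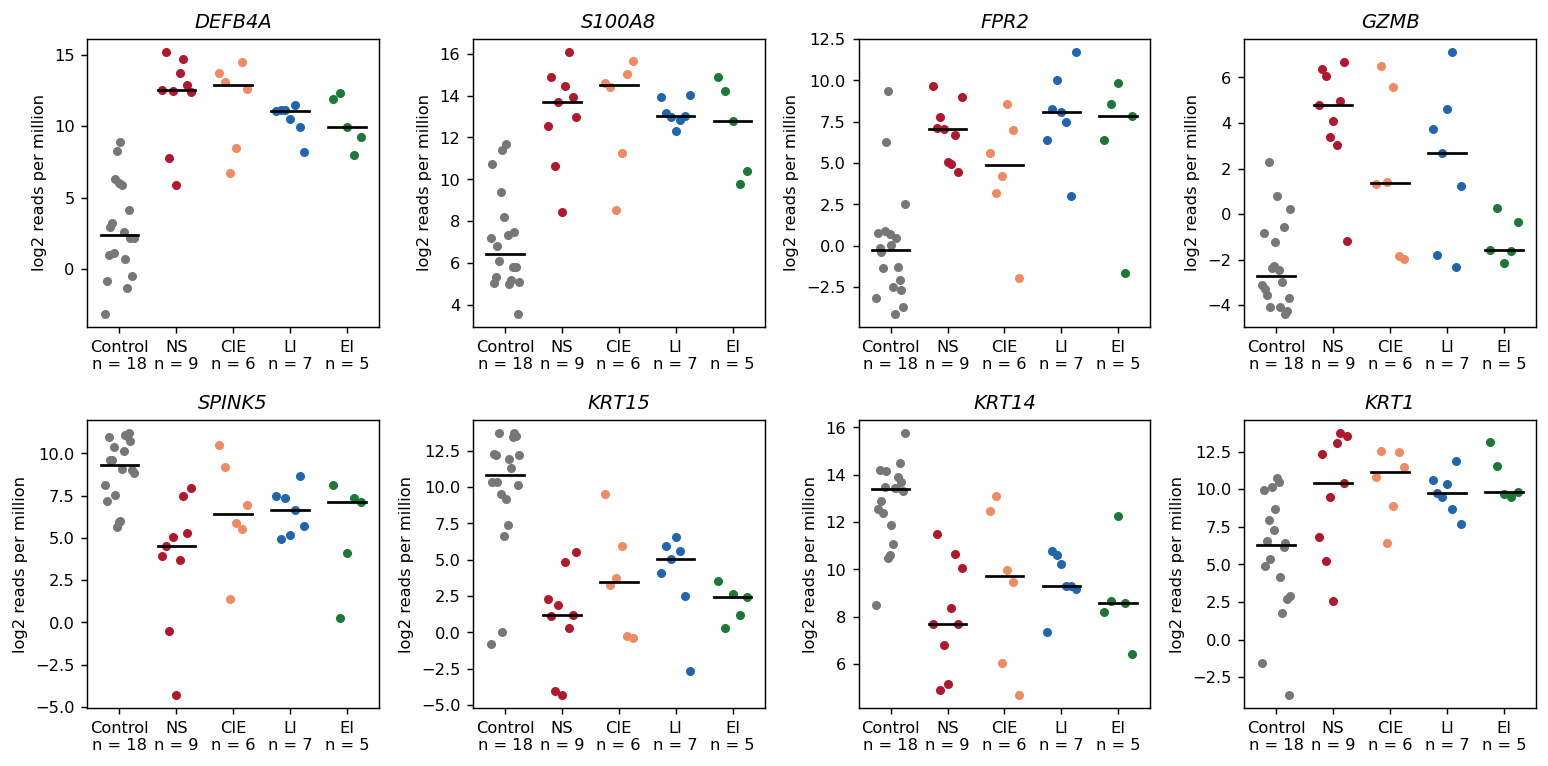
Levels of 8 genes in each library, by group, in log2 CPM. Bars are medians. SPINK5 is mutated in Netherton syndrome and KRT1 in epidermolytic ichthyosis.

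The genes whose variants cause these disorders did not move as a group. SPINK5, which restrains the kallikreins that split corneocytes apart, fell in NS (-5.34 ± 0.98, adjusted p = 8.41e-05, 9 of 9 libraries lower) and in EI (-3.60 ± 1.22, adjusted p = 0.025, lost without EI replicate 2 or 3). Its changes in CIE (-2.43 ± 1.14, adjusted p = 0.245) and LI (-2.45 ± 1.07, adjusted p = 0.115) did not pass. Nor did its difference between NS and CIE (-2.91 ± 1.27, adjusted p = 0.265), LI (-2.88 ± 1.22, adjusted p = 0.411) or EI (-1.74 ± 1.35, adjusted p = 0.363), so the fall is not shown to be particular to NS. KRT1 rose in NS (4.08 ± 1.19, adjusted p = 0.0111), LI (4.17 ± 1.30, adjusted p = 0.0279, lost without LI replicate 6) and EI (5.13 ± 1.48, adjusted p = 0.00941), the disease in which it is mutated, and missed the threshold in CIE (4.84 ± 1.38, adjusted p = 0.0564). Its partner KRT10 changed by -0.51 in NS, 1.59 in CIE, 0.44 in LI and 1.26 in EI (adjusted p 0.773, 0.369, 0.782 and 0.346). TGM1 changed by 0.52 in NS, 2.14 in CIE, 0.27 in LI and 1.46 in EI (adjusted p 0.723, 0.164, 0.85 and 0.208). The lipoxygenase gene ALOX12B changed by 2.19 in NS, 3.22 in CIE, 2.29 in LI and 2.22 in EI (adjusted p 0.0815, 0.0878, 0.0991 and 0.111). The ceramide gene NIPAL4 changed by 0.18 in NS, 1.34 in CIE, 0.55 in LI and 2.19 in EI (adjusted p 0.929, 0.459, 0.735 and 0.109), and none of these 4 genes passed in any disease. The list of 27 measured ichthyosis genes gave 2 higher and 4 lower of 27, adjusted p = 0.936 in NS, 0 higher and 0 lower of 27, adjusted p = 0.221 in CIE, 2 higher and 1 lower of 27, adjusted p = 0.761 in LI and 2 higher and 5 lower of 27, adjusted p = 0.846 in EI. FLG, the filaggrin gene, gave 1.56 in NS, 2.04 in CIE, 1.86 in LI and 2.69 in EI (adjusted p 0.283, 0.295, 0.199 and 0.0653). MKI67, a mark of dividing cells, gave 0.89 in NS, 0.63 in CIE and 0.23 in LI (adjusted p 0.582, 0.745 and 0.898), with 1 read over the 5 EI libraries.

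The 4 disorders share a core of rises. In the mean of the 4 against Control, 1604 genes rose and 2381 fell, led by DEFB4A (8.31 ± 0.79), LCE3A (7.37 ± 0.77), S100A7A (7.06 ± 0.82), S100A12 (7.02 ± 0.82) and CCL20 (6.84 ± 0.77), each with adjusted p at most 4.68e-09 and higher in 25 or more of 27 patient libraries. The falls were led by KRT15 (-7.21 ± 0.99), CXCL14 (-6.71 ± 1.03), SOSTDC1 (-6.48 ± 0.84), WFDC3 (-6.44 ± 0.88) and KRT5 (-6.28 ± 0.93; adjusted p at most 3.82e-06, 27 of 27 lower). In each of the 4 comparisons on its own, 59 genes passed in the same direction, 45 higher and 14 lower. SERPINB3, PI3, SPRR2F and OASL were among the 45, and APOE, the chaperone clusterin (CLU, -5.17 ± 0.69), KRT14, the scavenger receptor SCARA3 (-4.20 ± 0.66) and METTL7A (-4.13 ± 0.63) among the 14 (adjusted p at most 5.75e-06 in the mean). All 4 comparisons share the same Control libraries, which by itself makes lists overlap. Simulated groups without a change gave a median of 0 higher and 0 lower, at most 0 and 16. Shared controls alone can thus give as many as 14 shared falls, though the usual simulation gave 0. Such groups are made to have few genes that pass, so these counts decide neither on the 45 rises nor on the 14 falls. Sets of the real sizes were not simulated for all 4 together. Without CIE replicate 5 the split was 23 higher and 0 lower, and without CIE replicate 6 it was 37 and 0. Among libraries of 1 to 5 M reads 0 genes passed in all 4, against 348 without the 4 Control libraries described with NEUROG1. The share higher in the mean was 40.3 percent as deposited, 50.4 percent after quantile normalization and 81.8 percent with equal medians, with all-gene medians of -0.55, -0.13 and 0.37.

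Fold changes of the disorders also ran together. The correlation over all genes was 0.601 for NS and CIE, 0.721 for NS and LI, 0.514 for NS and EI, 0.723 for CIE and LI, 0.722 for CIE and EI and 0.739 for LI and EI, a median of 0.721. Shared controls explain a part: groups simulated without a change had a median of 0.278 and at most 0.678, and splitting the controls between the 2 comparisons left 0.603. For single pairs the highest simulated correlation passed the real one for NS and CIE (0.936), NS and LI (0.822) and NS and EI (0.831). It stayed below it for CIE and EI (0.699) and LI and EI (0.716), and only barely for CIE and LI (0.7223 against 0.7232). These pairs join the groups of lowest median depth. The simulated groups all have the Control mean, so a shift of a whole group with depth is not in them. Whether such a shift adds to these correlations was not tested. The covariance of fold changes was 2.43 with shared and 2.19 with split controls, against 0.231 simulated. Rises in common were compared with the highest t values of the simulated groups, as many as the real lists hold. NS and LI had 554 (simulated median 221.5, at most 532) and CIE and LI 57 (14, at most 47), more than any of 100 simulations. The 61 of NS and CIE and the 48 of CIE and EI were reached in 1, the 346 of LI and EI in 2 and the 277 of NS and EI in 9. Falls in common were 23 for NS and CIE, 198 for NS and LI, 293 for NS and EI, 26 for CIE and LI, 66 for CIE and EI and 325 for LI and EI. Among as many of the lowest simulated t values, 42, 7, 63, 16, 11 and 14 of 100 simulations gave as many in common. Shared controls alone can thus give overlaps of that size between sets of that length, but this does not account for the sets. Falls that passed in both simulated comparisons had a median of 0 in every pair. They numbered at most 39 for NS and LI, 39 for NS and EI and 54 for LI and EI. With CIE they reached 109 (NS), 234 (LI) and 834 (EI), more than the real ones. Genes changed in opposite directions numbered 10 for NS and EI, 2 for LI and EI and 0 for the other pairs. Among libraries of 1 to 5 M reads the median correlation was 0.465.

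Direct comparisons called genes between EI and the other disorders. Between NS and EI, 1522 genes were higher in NS and 224 lower. T and cytotoxic cell genes were higher in NS as a list (8 of 17 passed, 11 when adjusted over the list alone, adjusted p = 0.0129, adjusted p = 0.855 with an estimated correlation), and so were immune regulation genes (4 of 14 passed, 6 when adjusted over the list alone, adjusted p = 0.0474, adjusted p = 0.863 with an estimated correlation). Among the genes higher in NS were CIITA, the master switch of MHC class II (6.89 ± 1.49), the Langerhans cell lectin CD207 (6.26 ± 1.61), CRLF2 (5.54 ± 1.60) and the matrix factor SERPINF1 (6.74 ± 1.32). C1QC was at least 148-fold and GZMB at least 73.5-fold higher, both with 0 EI reads (all 6 adjusted p at most 0.0175). CD40, a costimulator of antigen-presenting cells, had 10066 reads in NS and 1 in EI, ELK4 3748 and 1, and ICOS 1548 and 3. The hair shaft genes KRTAP4-2 (-7.56 ± 2.03), KRTAP9-3 (-7.09 ± 2.12) and KRT31 (-5.89 ± 1.79) were lower in NS, though the hair list was not called (adjusted p = 0.0982), with CEBPA (-6.76 ± 1.66) and the zinc finger gene ZNF22 (-6.60 ± 1.82; adjusted p at most 0.0225). Without EI replicate 5 the calls of KRTAP9-3, KRT31 and CRLF2 were lost, as was KRT31 without EI replicate 2 and CRLF2 without EI replicate 3. The share higher in NS was 87.2 percent as deposited, 42.3 percent after quantile normalization and 2.35 percent with equal medians (all-gene medians 1.26, 0.03 and -1.54). With the number of detected genes as a covariate 15 genes passed, and among libraries of 1 to 5 M reads (3 NS, 3 EI) 0.

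Between CIE and EI, 97 genes were higher in CIE and 1 lower, a count that 9 of 100 splits of these libraries reached and that fell to 0 with only the groups compared. The epidermal differentiation factor TFAP2C (6.31 ± 1.21, adjusted p = 0.00394, 6 of 6 libraries) was higher. PLAA (at least 112-fold), the purine enzyme ATIC (at least 116-fold) and the mitochondrial GTPase NOA1 (at least 114-fold) had 0 EI reads (adjusted p at most 0.0303). ZNF165 was lower (-6.21 ± 1.42, adjusted p = 0.0191). ATIC lost its call in 5 of 11 fits with 1 library left out and ZNF165 in 2. Between LI and EI, 350 genes were higher in LI and 0 lower, a count that fell to 8 with only the groups compared and to 8 with the number of detected genes as a covariate. Among them were the kinases PKN2 (at least 425-fold) and CDK13 (at least 136-fold), the repair factor RNF169 (6.74 ± 1.30), the neutrophil leukotriene hydroxylase CYP4F3 (6.62 ± 1.39), the neutrophil receptor CXCR2 (5.96 ± 1.65) and the ductal keratin KRT19 (5.12 ± 1.40). Each was higher in 7 of 7 libraries, with adjusted p at most 0.0311. CXCR2 lost its call in 5 of 12 such fits and KRT19 in 6. With the recovered library sizes 28 genes were higher and 1 lower in CIE, and 39 and 0 in LI. Under the centring methods shares of 99.0 and 100 percent became 82.3 and 57.9 percent after quantile normalization and 0 and 0.864 percent with equal medians. Thinned to 1 M reads 71 genes were higher and 12 lower in CIE, and 113 and 4 in LI. 0 genes passed in either among libraries of 1 to 5 M reads, where 3 EI libraries remain. The all-gene medians were 0.50, -0.05 and -1.03 for CIE against EI and 0.90, -0.11 and -1.74 for LI against EI.

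Whether single genes tell NS, CIE and LI apart depends on the processing. As deposited, limma called 0 genes between NS and CIE (lowest adjusted p 0.0838; 1817 genes at unadjusted p under 0.05; 37 by a negative binomial model and 3 with voom weights), 0 between NS and LI (0.190; 1160; 2 and 0) and 0 between CIE and LI (0.47; 968; 0 and 0). Sample quality weights gave 1006, 119 and 769. Between NS and CIE 321 genes passed among libraries over 5 M reads, 117 with equal medians, 45 after quantile normalization and 30 without CIE replicate 1. Between NS and LI 43 passed with only the groups compared and 29 after quantile normalization, and between CIE and LI at most 1 in settings other than the weights. Changes of log2 3 simulated in the first disease of each pair were recovered for 77, 83 and 72 percent of genes, so smaller differences can be missed. The simulated genes varied independently of each other, so real differences of that size can be missed too. By lists, T and cytotoxic cell genes were higher in NS than in CIE (0 of 17 passed, 5 when adjusted over the list alone, adjusted p = 0.0267, adjusted p = 0.368 with an estimated correlation) and LI (0 of 17 passed, 11 when adjusted over the list alone, adjusted p = 0.0454, adjusted p = 0.215 with an estimated correlation). Dendritic cell genes (0 of 24 passed, 15 when adjusted over the list alone, adjusted p = 0.0267, adjusted p = 0.366 with an estimated correlation), immune regulation genes (0 of 14 passed, 9 when adjusted over the list alone, adjusted p = 0.0248, adjusted p = 0.366 with an estimated correlation) and the Th2 list (0 of 19 passed, 7 when adjusted over the list alone, adjusted p = 0.0267, adjusted p = 0.458 with an estimated correlation) were higher in NS than in CIE. The JAK-STAT and heat shock lists were also called higher and the junction list lower in NS against CIE (each adjusted p = 0.0267, 0.458, 0.458 and 0.0737 with an estimated correlation). Heat shock genes were higher in NS than in LI too (0 of 18 passed, 1 when adjusted over the list alone, adjusted p = 0.0454, adjusted p = 0.215 with an estimated correlation). No list was called between CIE and LI, CIE and EI or LI and EI.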

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

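The tests of the excess of falls in EI and those of the olfactory receptor reads were chosen after the result was seen, the splits of the libraries before. The first pattern is the olfactory receptor reads, silent genes in skin, which stood out in NS replicate 9 (23653 against 19 to 3023 CPM in the other NS libraries), CIE replicate 3 (18744 against 24.2 to 2582) and LI replicate 5 (22553 against 133 to 8964) and were higher in EI as a group (exact permutation p = 0.00574, adjusted 0.0229 over 4 diseases). A lifted floor of shallow libraries is not enough, as the ratio of median CPM between EI and Control, which has no floor, was 57.9. Genomic DNA spread evenly over the 285 genes would touch nearly all of them with the 2472 to 5298 such reads of each EI library. A read was found for a median of 42.8 percent (41.8 to 54.7), against 100 percent in NS replicate 9. The shortfall was not particular to EI, with 68.4 percent in Control replicate 11 and 51.2 in CIE replicate 4, where an even spread gives 100. LI replicate 5 reached 99.7 percent. The EI share lay between the outcomes set for either side, so the test cannot decide. Genomic DNA stays open in EI, also as copies of few fragments. Expression in diseased skin stays open too, since 2 of 18 Control libraries lay above the EI median, too few to exclude it. Those 2 (replicates 2 and 10) were the shallowest of Control, with 1.40 and 1.10 M reads. In CIE the 2 libraries over 5 M reads had 24.2 and 27.7 CPM, against 1489 to 18744 in the others. High values thus went with low depth in these groups, and in EI depth and disease cannot be told apart.

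The second pattern is the excess of falls in EI, and with it the differences between disorders: 1746 genes between NS and EI, 98 between CIE and EI and 350 between LI and EI, of which 1522, 97 and 350 were lower in EI. After quantile normalization 42.3, 82.3 and 57.9 percent were lower in EI and with equal medians 2.35, 0 and 0.864 percent. These methods centre each library and so move the split without fixing it. With the recovered library sizes 469 of 683, 28 of 29 and 39 of 39 were lower in EI. If lower depth of the EI libraries were the cause, the all-gene median should return to near 0 with every library thinned to 1 M reads. It was -1.06 there (-1.19 to -0.91 with 1 library left out, 3 EI and 18 Control libraries) against -1.23 in all libraries, with 283 genes higher and 1578 lower, so the number of reads is not the whole cause. Poorer libraries, of which low depth is a sign, stay open: among libraries of 1 to 5 M reads, where 7 shallow Control libraries remain, the median was -0.39 (-0.385 before rounding), between the outcomes set for either side. With the number of detected genes as a covariate it was -0.09, with 109 genes higher and 147 lower. If the scaling by the authors were the whole cause, the median should return to near 0 with the recovered library sizes, and it was -0.91 (-0.913 before rounding, -1.03 to -0.77 with 1 library left out), so it is not. Quantile normalization gives every library the same distribution of values, which takes out a shift of all genes whatever its source. The even split after it (52.9 percent higher) therefore cannot decide, and no biological explanation was tested. The rises of DEFB4A, S100A8 and the neutrophil list in EI are not part of this excess.

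Splits of the same libraries into other groups tell whether chance can give as many changed genes as the real split, which counts as 1. Only the real split, 1 of 100, reached the count for NS (real 1927, highest other 1770), LI (real 1473, highest other 456) and EI (real 3298, highest other 1550). The same held for the mean of the 4 (real 3985, highest other 127), NS against EI (real 1746, highest other 209) and LI against EI (real 350, highest other 242). Chance alone is unlikely there, though 100 splits cannot exclude it, and for NS another split came close. It stays open for CIE, with 5 of 100 splits (real 148, highest other 1075), and for CIE against EI, with 9 of 100 splits (real 98, highest other 500). For NS against CIE, NS against LI and CIE against LI, with 0 genes each, the comparison is void, since all 100 of 100 splits reach 0 by definition.

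Single libraries stood apart in 20 of 270 Dixon tests, where chance gives about 5 percent or 1 in 20. NS replicate 10 had fewer genes with a read (7848 against 10018 to 11412) and low immune cell genes: CD86 (-1.20 against 6.76 to 9.36), GZMB (-1.20 against 3.02 to 6.67), STAT4 (-1.20 against 1.61 to 3.88) and TIGIT (-1.20 against 2.10 to 4.41) without a read, IL7R (0.39 against 6.67 to 9.33) and LYZ (8.23 against 10.60 to 11.91), all in log2 CPM. The same library was high in IL4R (7.64 against 5.96 to 6.69). NS replicate 6 was low in S100A12 (2.80 against 6.64 to 10.06) and VWF (-2.71 against 2.31 to 6.75). CIE replicate 3 was low in S100A12 (1.39 against 6.78 to 9.00) and the ceramide gene NIPAL4 (1.39 against 7.13 to 8.59). Both stand without a read in that library, the shallowest of all with 0.112 M reads, so neither shows a loss in that patient. LI replicate 1 was low in KRT5 (1.25 against 7.06 to 9.76) and MX1 (-0.87 against 4.61 to 6.84). LI replicate 4 was high in EFEMP1 (4.37 against -2.69 to -0.50) and PIK3C2G (3.23 against -2.82 to -1.13), which rest on at most 7 and on 2 reads in a library of 0.212 M reads, and LI replicate 7 was low in SPRR2D (10.78 against 13.61 to 14.88). None of these causes was tested.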

How the results depend on the processing

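The strata, thinning, recovered library sizes, negative binomial model, olfactory receptor covariate and the sets of libraries left out together were chosen after the results were seen, the other alternatives before. Each sentence below the main counts gives the values that moved by more than 1.5 times, and the cause was not tested unless stated. Main counts of genes were NS 1927, CIE 148, LI 1473, EI 3298, the mean 3985, NS-CIE 0, NS-LI 0, NS-EI 1746, CIE-LI 0, CIE-EI 98 and LI-EI 350, of lists NS 23, CIE 9, LI 19 and EI 12, of genes changed alike in all 4 59, and the median correlation was 0.721.

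Sample quality weights gave genes NS 6061, CIE 2012, LI 5630, EI 5820, the mean 8016, NS-CIE 1006, NS-LI 119, NS-EI 2626, CIE-LI 769, CIE-EI 2821, LI-EI 575, lists CIE 23, all 4 804. Quantile normalization gave genes CIE 230, NS-CIE 45, NS-LI 29, CIE-EI 51, LI-EI 121, lists EI 22, all 4 108. Equal medians gave genes CIE 246, NS-CIE 117, CIE-EI 8, LI-EI 579, lists CIE 24, LI 10, EI 29, all 4 122. The upper part of genes by mean gave genes NS 716, LI 520, the mean 1788, CIE-EI 212, LI-EI 581, lists CIE 1. Only the groups compared gave genes CIE 82, NS-CIE 2, NS-LI 43, CIE-EI 0, LI-EI 8. The number of detected genes as a covariate gave genes CIE 39, EI 256, the mean 1827, NS-CIE 8, NS-LI 3, NS-EI 15, CIE-EI 29, LI-EI 8, lists EI 4, all 4 15, correlation 0.583. Voom weights gave genes NS-CIE 3, CIE-EI 51, LI-EI 219. The negative binomial model gave genes LI 2384, NS-CIE 37, NS-LI 2, NS-EI 631, CIE-EI 327. Camera with a preset correlation gave lists CIE 23, EI 24. Camera with an estimated correlation gave lists NS 9, CIE 2, LI 2, EI 0. Libraries of 1 to 5 M reads gave genes NS 21, CIE 15, LI 10, EI 0, the mean 38, NS-LI 3, NS-EI 0, CIE-LI 1, CIE-EI 0, LI-EI 0, lists NS 3, CIE 0, LI 2, EI 0, all 4 0, correlation 0.465. Libraries over 5 M reads gave genes NS 4612, CIE 98, NS-CIE 321. Without libraries under 1 M reads there were genes CIE 85, EI 1470, NS-LI 6, NS-EI 561, LI-EI 121, lists CIE 4, LI 10, EI 5, all 4 28. Thinning to 1 M reads gave genes CIE 77, LI 894, EI 1861, NS-EI 652, LI-EI 117, lists CIE 3, LI 11, all 4 33. The recovered library sizes gave genes NS-EI 683, CIE-EI 29, LI-EI 39. The olfactory receptor share as a covariate gave genes CIE 85, LI 751, EI 572, the mean 1775, NS-EI 370, CIE-EI 34, lists CIE 2, LI 12, EI 6, all 4 24. Without 8 libraries rich in olfactory receptor reads there were genes CIE 336, NS-CIE 2, NS-LI 8, NS-EI 813, CIE-LI 1, CIE-EI 217, LI-EI 215. Without 4 Control libraries with NEUROG1 reads there were genes CIE 978, LI 3073, CIE-EI 160, lists CIE 14, all 4 348. Without NS libraries 4 and 6 there were genes NS-LI 1, NS-EI 757, CIE-EI 60. Leaving out the trend or using a robust prior moved none. The planned DESeq2 and edgeR count tests and the other pseudocount were not run, as the deposited unit is log2.

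With the replicate number as a replicate block the values were genes NS 776, CIE 32, LI 369, EI 858, the mean 516, CIE-EI 11, LI-EI 53, lists CIE 3, LI 11, EI 4, all 4 22. Equal numbers do not pair people: deviations from the group mean correlated by a median of -0.021 over 58 pairs of equal number. What the block removes was not tested.

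Leaving out 1 library at a time gave these ranges, with the replicate whose absence moved a count and the count without it in square brackets. Genes NS 1615 to 2145, genes CIE 29 to 484 (moved by Control 1 [295], 2 [269], 3 [95], 6 [89], 8 [253], 10 [290], 12 [84], 13 [87], 14 [86], 16 [92], 17 [89], 19 [81], CIE 1 [484], 2 [398], 3 [79], 4 [95], 5 [29], 6 [55]), genes LI 989 to 1972. Genes EI 2056 to 3993 (moved by EI 5 [2056]), genes the mean 3423 to 4695, genes NS-CIE 0 to 30 (moved by NS 10 [5], CIE 1 [30], 2 [23], 4 [4]). Genes NS-LI 0 to 7 (moved by NS 10 [7]), genes NS-EI 809 to 2414 (moved by EI 5 [809]), genes CIE-LI 0 to 1 (moved by CIE 4 [1]). Genes CIE-EI 29 to 244 (moved by CIE 1 [32], 2 [29], 3 [244], 4 [64], EI 1 [223], 3 [155], 4 [63], 5 [47]), genes LI-EI 118 to 577 (moved by LI 3 [187], EI 3 [577], 4 [211], 5 [118]), lists NS 21 to 24. Lists CIE 2 to 13 (moved by CIE 1 [4], 3 [4], 4 [3], 5 [2]), lists LI 13 to 21, lists EI 5 to 13 (moved by EI 2 [5], 3 [7]). All 4 23 to 98 (moved by Control 8 [98], 10 [96], CIE 3 [39], 5 [23], 6 [37]), correlation 0.643 to 0.746.

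Named genes turned direction in 7 cases. Among libraries of 1 to 5 M reads CCL22 in NS became -0.045 (main 3.50), KRT31 in NS 0.32 (main -3.86), CCL13 in EI -0.53 (main 4.30) and HLA-DRA in NS-EI -0.47 (main 3.26). CCL13 in EI became -0.43 with the detected genes as a covariate, and with equal medians MKI67 in EI became 2.61 (main -0.05) and RPS6 in EI 0.22 (main -2.45), where the scaling alone sets the sign. Of the lists called, those that kept the call with any 1 library left out were 21 of 23 in NS, 2 of 9 in CIE, 13 of 19 in LI and 4 of 12 in EI, where the Th2 list lost it in 15 of 23 fits. Of the named genes called in a comparison, those that kept the call with any 1 library left out were 56 of 57 in NS, 12 of 27 in CIE, 46 of 50 in LI, 39 of 46 in EI, 25 of 25 in the mean, 13 of 21 in NS-EI, 4 of 6 in CIE-EI and 5 of 7 in LI-EI. Without NS libraries 4 and 6 the cornified layer list was called higher in NS (median 2.04, adjusted p = 0.00507) and in LI (median 1.67, adjusted p = 0.0392).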

Other observations

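Of the tests of the fall of basal genes below, those of depth and DNA in NS were set before their results were seen and those of dilution and of the other diseases after, and the NEUROG1 libraries were noticed only after the values were seen. As deposited, the cornified layer list of 32 genes was not called in any disease (medians 0.95 in NS, 1.64 in CIE, 1.68 in LI and 1.41 in EI, adjusted p 0.437, 0.196, 0.109 and 0.282). Of its genes, CNFN rose in CIE (3.59 ± 0.90, adjusted p = 0.0285). HRNR passed as higher in all 4 diseases, among them NS (6.33 ± 1.09, adjusted p = 3.11e-05) and LI (4.44 ± 1.19, adjusted p = 0.00972). With sample quality weights it was called in NS (median 1.66, adjusted p = 0.00839) and LI (2.98, adjusted p = 0.0178), and with equal medians in CIE (2.77, adjusted p = 0.0392) and EI (4.08, adjusted p = 0.00267). The lipid barrier list (34 genes, adjusted p 0.611, 0.422, 0.524 and 0.54), the proteases and their inhibitors (35 genes, 0.645, 0.401, 0.431 and 0.651) and the suprabasal keratins and desmosomes (18 genes, 0.0951, 0.973, 0.517 and 0.54) were not called either. Proliferation genes gave 0 rises and 0 falls of 21 in NS and CIE, 0 and 1 in LI, and 1 and 3 in EI (adjusted p 0.234, 0.94, 0.944 and 0.611). Among cells and appendages, melanocyte (adjusted p 0.618, 0.791, 0.14 and 0.2), eccrine (0.151, 0.94, 0.194 and 0.54), sebaceous (0.936, 0.94, 0.51 and 0.651) and red blood cell genes (0.618, 0.94, 0.0585 and 0.15) were not called.

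Several lists were called in some diseases through a few genes. Mast cell and eosinophil genes, of which 4 were measured, rose in NS (2 of 4 rose, adjusted p = 0.00211, adjusted p = 0.206 with an estimated correlation), LI (2 of 4 rose, adjusted p = 0.00573, adjusted p = 0.238 with an estimated correlation) and EI (2 of 4 rose, 3 higher when adjusted over the list alone, adjusted p = 0.0192, adjusted p = 0.155 with an estimated correlation), where the eosinophil gene CLC rested on 79 LI and 24 EI reads in 2 libraries each. NRF2 targets of the oxidative stress response rose in NS (5 of 19 rose and 2 fell, 5 higher and 3 lower when adjusted over the list alone, adjusted p = 0.00572, adjusted p = 0.284 with an estimated correlation) and LI (2 of 19 rose, 3 higher when adjusted over the list alone, adjusted p = 0.001, adjusted p = 0.152 with an estimated correlation). Heat shock genes rose in NS (2 of 18 rose and 1 fell, adjusted p = 0.00252, adjusted p = 0.287 with an estimated correlation), as did targets of the aryl hydrocarbon receptor (1 of 6 rose, adjusted p = 0.0456, adjusted p = 0.624 with an estimated correlation), the latter a call lost in 16 of 27 fits with 1 library left out. Sterol synthesis genes were not called in NS (0 higher and 2 lower of 18, adjusted p = 0.168). B and plasma cells, with 2 measured genes, were not tested.

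The joint fall of basal and rise of neutrophil genes could come from the sampling and not from the disease. Dilution of all keratinocyte transcripts by immune cells would pull the cornified layer list down with the basal list. In NS the cornified median was 0.95 (0.954 before rounding, list adjusted p 0.437), not lower. That list cannot decide, as it holds genes that rose, such as HRNR, and with the replicate block its median was 0.07 (adjusted p = 0.886). The junction list fell in NS (adjusted p = 0.000829), and suprabasal keratins and desmosomes pointed down without a call (0.0951). Dilution thus stays open. Tape that takes fewer living cells would have the same effect on the basal list and was not tested. Lower depth is unlikely to be the cause in NS, whose libraries were as deep as Control (5.82 and 5.83 M reads): the basal median was -5.71 and the neutrophil median 5.68 among libraries over 5 M reads, and -2.65 and 4.25 with every library thinned to 1 M. The 3 NS libraries of 1 to 5 M reads gave a basal median of -0.83 (adjusted p = 0.689). In CIE, LI and EI depth stays open. Thinned, their basal medians were -2.52, -2.66 and -2.06 against -2.53, -2.14 and -2.05 in all libraries, but the calls were lost with fewer libraries (adjusted p 0.0742, 0.0625 and 0.174). Among libraries of 1 to 5 M reads the medians were -1.89, -0.36 and 0.03, and in CIE over 5 M -1.24 (adjusted p = 0.109). Genomic DNA reads are unlikely in NS, with medians of -4.22 and 5.41 without the 8 libraries rich in olfactory receptor reads, and open in the others. Without those libraries the basal medians were -2.83, -3.17 and -2.25 (adjusted p 0.032, 0.0398 and 0.16). With the olfactory receptor share as a covariate they shrank to -2.02, -1.40 and -0.99 (-0.992 before rounding, adjusted p 0.0614, 0.313 and 0.339).

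NEUROG1, a neuronal transcription factor gene, reached log2 10.03 to 13.88 in 4 Control libraries (replicates 8 to 11), against at most 6.84 in the 41 others. In Control replicate 10 it held 1.95 percent of the recovered reads. Without these 4 libraries the numbers of changed genes rose to 2525 in NS, 978 in CIE, 3073 in LI and 4935 in EI. The source of the reads was not tested. Olfactory receptor genes higher in a disease numbered 9 of 285 in NS, 1 in CIE, 111 in LI and 93 in EI, and other single-exon coding genes 23, 1, 87 and 61 of 426, so a part of the LI and EI rises among such genes is of uncertain origin. Multi-exon genes, which DNA reads touch less, gave 709 rises and 513 falls in LI and 542 and 2501 in EI.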
